A study of Mus musculus with 44 samples.

How the data were processed

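Whole mouse testes were measured by targeted RNA sequencing, in which primer pairs copy a fixed panel of transcript pieces (amplicons, called targets here) and the reads of each are counted. Per the labels, 50 ng of total RNA with RIN values above 9.0 went into each TruSeq Targeted RNA Expression library. The panel holds 104 targets of 103 genes, E2f3 being covered by 2. All 44 samples were placed in 9 groups from the genotype, age and animal stated in the labels, and 0 columns of the tables were left without a sample. The animal numbers in the titles differ between samples, so each library was treated as 1 animal. RbKO and E2f3KO stand for cre/lox knockouts in Sertoli cells, the somatic cells that nurse germ cells inside the seminiferous tubules. RbKO_E2f3het animals carry cre with floxed Rb1 alleles and 1 floxed E2f3 allele, and dKO animals have floxed alleles of both genes. The animals called WT in the labels are cre-negative lox carriers where the adult titles state it. The title of 2.5mo_WT replicate 5 states no cre status.

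For each of 3 tables (2 months, 5 months, and 2.5 months with 10-day-old animals) the authors deposited read counts per target, which were used for all tests. The deposited tables of normalized hits hold a score per target and sample. That score was rebuilt from the counts as the log2 count (0 set to 1), minus the sample median, minus the target median, divided by the target's mean absolute deviation. Within a tolerance of 1e-09, 100.0% of the values in each table were rebuilt, so the score is scaled by each target's own spread and is no fold change. The aligner, the counting software and the genome build of the authors are not given in the sources used here. All 104 targets were matched to GENCODE M21 (GRCm38) by the transcript accession in the amplicon name, from which the gene positions were taken.

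Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM scaling, quasi-likelihood F test, two-sided), with targets kept at a mean count of at least 10. Separate fits were made for the 10 samples of 2 months, the 10 of 5 months, these 20 together for the difference between the ages, the 19 adult samples of 2.5 months, and the 10 of P10_WT and 2.5mo_WT. P values were adjusted by Benjamini-Hochberg over the tested targets of each comparison, and a target is called where its adjusted p is under 0.05. Every adjusted p for a single target comes from edgeR unless another tool is named. Levels are given as TMM-scaled CPM (counts scaled to a common panel total) within each fit, as mean ± SD over animals. Because the panel is small, a CPM is a share of the panel and not of all transcripts. Intervals of fold changes are the estimate with its SE at the 95% level. For targets with 1 to 3 counts in a group, the ratio is given with its exact binomial interval. A group with no counts was set to a floor of 3 counts over the group. PCR reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

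Of 17 gene lists, those with at least 3 tested targets were tested with fry of limma 3.58.1 on log2 CPM (prior count 2). Its PValue tests whether a list's targets move, on balance, one way, and PValue.Mixed whether they change in either direction. Neither compares the list with other targets. List p values were adjusted over the lists of each comparison. The lists were the RB and E2F family, cyclins and S phase, apoptosis and p53, adult Sertoli cell, immature Sertoli cell, Sertoli-derived niche factors, undifferentiated spermatogonia, differentiating spermatogonia, meiotic spermatocytes, Leydig cell, peritubular and stroma, and reference genes. Lists of other cell types with fewer targets on the panel were not tested. In these whole-testis libraries a list name stands for its targets, and not for a count of cells.

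The lists, the comparisons, the tests, the other settings to try and the rule for naming targets were fixed before the data were examined. The rule names E2f3 and Rb1 always, then the called targets of each comparison, or the 25 with the largest change if there are more, and members of the lists as examples. These other settings were DESeq2 1.42.0, scaling by the total alone or by the reference genes, limma on the deposited score, no filter and a mean of at least 50, other sets of samples in the fit, lox/lox controls alone, and leaving out each library in turn. For a named target or a list, a change of sign was counted only where the value passed the threshold in at least 1 of the 2 fits compared. Totals ran from 36679 to 252993 counts per library. Replicate libraries of 1 group differed by at least 32.6 times the variance of counting (the smallest chi-square per degree of freedom over pairs), so animals and library making, and not depth, set most of the error. On simulated data with known changes, edgeR called 73.4% of targets moved by 2 on the log2 scale in the 2-month design and 57.1% in the RbKO design. It called 35.6% and 15.8% of those moved by 1, and between 0.66% and 1.04% of the unmoved ones over the designs tested. The simulation drew each target on its own, so differences that many targets share between replicate libraries are not part of these shares.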

Results

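Testes of 44 mice were measured on a panel of 104 targets. At 2 months there were 5 animals with Sertoli-cell loss of E2f3 (2mo_E2f3KO) and 5 controls (2mo_WT), and at 5 months again 5 of each. At 2.5 months there were 4 RbKO, 5 RbKO_E2f3het, 5 dKO and 5 WT animals of a mixed strain, and 5 P10_WT animals of 10 days came from C57BL/6. Total counts per library ran from 202806 to 230925 in 2mo_WT and from 134827 to 233945 in 2mo_E2f3KO. They ran from 145148 to 222987 in 5mo_WT and from 187606 to 252365 in 5mo_E2f3KO. At 2.5 months they ran from 205862 to 252993 in WT, 170708 to 213264 in RbKO, 193783 to 219538 in RbKO_E2f3het and 127508 to 182874 in dKO, and in P10_WT from 36679 to 164661. In 3 libraries over 20% of the targets had a count of 0, namely RbKO replicate 3 (23.1%), dKO replicate 3 (22.1%) and P10_WT replicate 4 (21.2%).

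The targeted genes themselves were compared first, since the labels give their loss in Sertoli cells as the treatment. Rb1, the retinoblastoma tumour suppressor that holds E2F factors in check, was lower in RbKO testes, at 1239 ± 333 CPM (SD, n = 4) against 4354 ± 1588 in WT (n = 5). That is a log2 fold change of -1.81 (95% interval -2.84 to -0.78, adjusted p 0.00955), with 4 of 4 RbKO animals below the WT mean. Rb1 stood at 2907 ± 1503 CPM in RbKO_E2f3het and 2085 ± 1277 in dKO (SD, n = 5 each), and neither passed the test against WT (adjusted p 0.958 and 0.472). E2f3, an activating E2F factor of the cell cycle, was read by amplicons 7231985 and 7231987, and neither was called in any E2f3KO or dKO group. At amplicon 7231987 the 2-month knockouts had 44.0 ± 65.6 CPM against 339 ± 106 in WT (SD, n = 5 each), and 3 of 5 knockout libraries had a count of 0. Its log2 fold change of -2.89 (SE 1.18) had an adjusted p of 0.955. At 5 months the same amplicon had 153 ± 121 CPM against 309 ± 198 (log2 fold change -1.01, SE 0.68, adjusted p 0.576), and the difference between the ages was not called (2.01, SE 1.28, adjusted p 0.834). Amplicon 7231985 had 1414 ± 607 CPM against 1299 ± 526 at 2 months and 1206 ± 156 against 1477 ± 331 at 5 months. In dKO it had 609 ± 593 CPM against 953 ± 686 in WT (log2 fold change -0.64, SE 0.79). Amplicon 7231987 had 356 ± 293 CPM in dKO against 325 ± 224 in WT. In RbKO amplicon 7231985 had 2456 ± 1236 CPM (SD, n = 4), with 4 of 4 animals above the WT mean (1.37, SE 0.83, adjusted p 0.227). Amplicon 7231987 went the other way there, at 129 ± 142 CPM (-1.32, SE 1.19, adjusted p 0.428). In P10_WT against 2.5mo_WT they changed by 1.06 (SE 0.62, adjusted p 0.211) and -0.18 (SE 1.41, adjusted p 0.930). E2f3 lies on chromosome 13 (29906575 to 29986063, minus strand) and Rb1 on chromosome 14 (73183673 to 73325822, minus strand) of GRCm38. The sources used here do not state whether the amplicons lie in the deleted parts, and whole testis also holds cells in which the genes are intact.

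**Figure D1:**
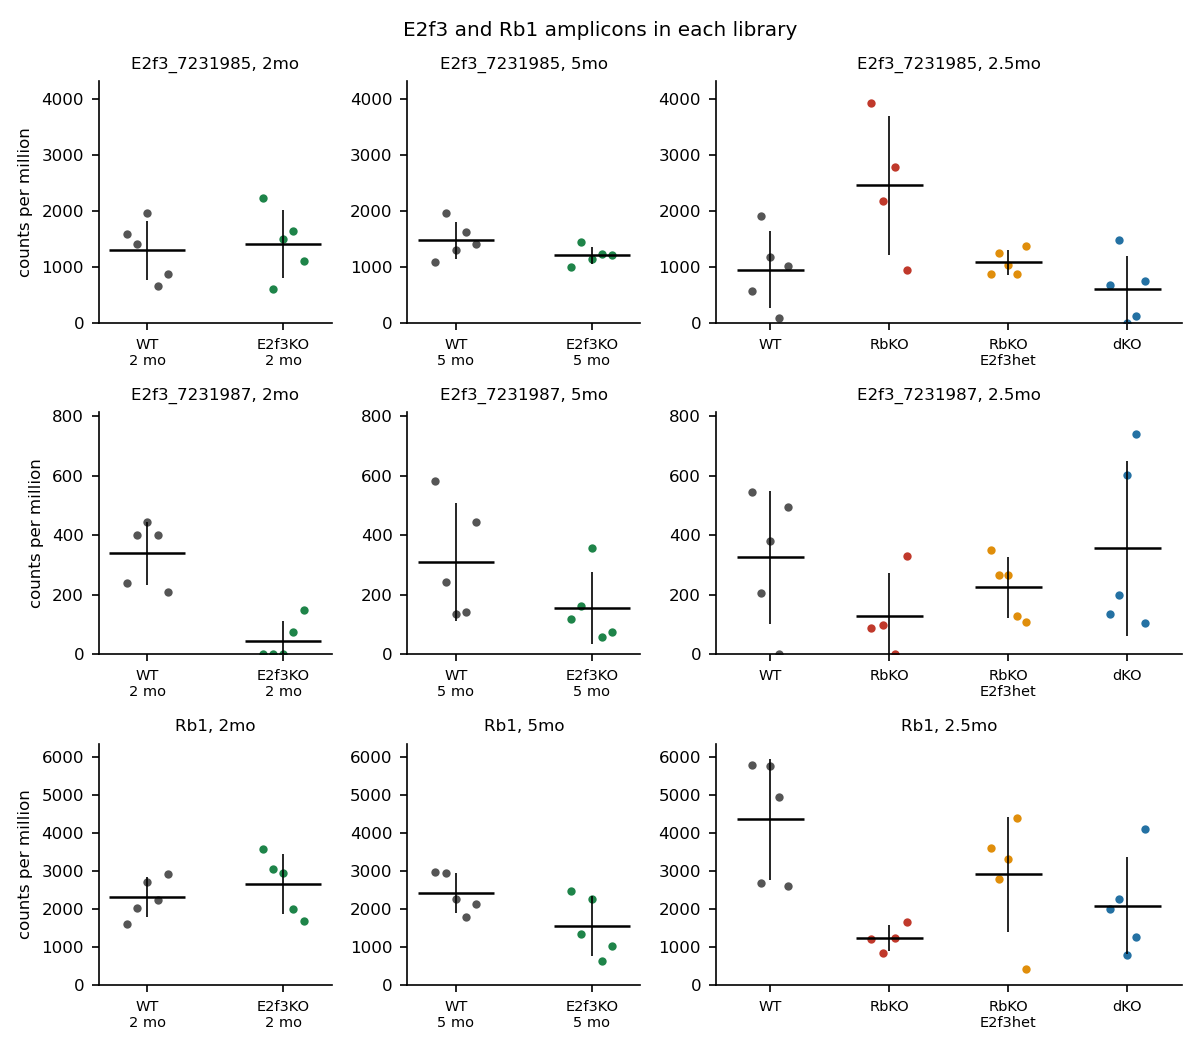
Levels of the E2f3 amplicons and of Rb1 (CPM, y axis) in each animal of the adult groups (x axis), with bars at the mean and vertical lines for ±SD, drawn down to 0 at most. The RbKO animals, with a mean of 1239 CPM for Rb1, lie below the WT animals at 2.5 months, with a mean of 4354.

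The comparison of E2f3KO with WT asks what loss of E2f3 in Sertoli cells does to the adult testis at 2 and at 5 months. Cell-cycle, germ-cell and steroidogenic targets showed no called change at either age. At 2 months, 98 targets were tested with edgeR and 0 were called, with 3 at an unadjusted p under 0.05: E2f3 amplicon 7231987, Jun (-1.22 on the log2 scale), an immediate early transcription factor, and Rhox5 (0.50), a homeobox gene of Sertoli cells. DESeq2 called 0 (5 unadjusted) and limma on the score 0 (3 unadjusted). At 5 months, 99 were tested and 0 called, with 6 at an unadjusted p under 0.05. Of these Bax (-0.76), Cx3cl1 (-1.46), Dnmt1 (-0.72), Myh11 (-0.84) and Rbl2 (-0.63) were lower in E2f3KO and Kit (0.63), the stem cell factor receptor of differentiating spermatogonia, was higher. DESeq2 called 0 (9 unadjusted) and limma on the score 0 (6 unadjusted). The smallest adjusted p was 0.955 at 2 months and 0.521 at 5 months. These uncalled targets are named because they are few, after their values were seen. The difference between the ages gave 0 called of 99 (3 unadjusted; DESeq2 0, with 5 unadjusted; limma 0, with 1).

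None of the 12 gene lists tested was called in E2f3KO at either age, one way or in either direction. At 2 months the smallest one-way adjusted p was 0.675, and 0 targets were called adjusted over the list alone. In either direction the smallest was that of the RB and E2F family, which holds E2f3 (0.316; 0.0263 unadjusted). At 5 months the adult Sertoli cell list, with markers such as Sox9, Wt1 and Inha, had the smallest one-way adjusted p (0.200, upward, median log2 fold change 0.17), and the RB and E2F family the smallest in either direction (0.855). Adjusted over the list alone, 1 target was called at 5 months, in the peritubular list. The Sertoli-derived niche factors (Gdnf, Inhba and Inhbb), signals to spermatogonial stem cells, had adjusted p 0.802 at 2 months and 0.859 at 5 months. For the difference between the ages the smallest one-way list adjusted p was 0.457, for the adult Sertoli cell list. That list passed without 2mo_WT replicate 5 (0.0274), 2mo_E2f3KO replicate 1 (0.0297) or 5 (0.0418), 5mo_WT replicate 4 (0.0447) or 5mo_E2f3KO replicate 3 (0.0286). The direction of the test, the median and the mean differed in sign for 4 lists at 2 months (RB and E2F family, both Sertoli cell lists, niche factors) and 3 at 5 months (differentiating spermatogonia, meiotic spermatocytes, peritubular). They did so for 3 in the difference between the ages (RB and E2F family, niche factors, Leydig cell). On simulated data with changes of 1 on the log2 scale, edgeR called 35.6% at 2 months and 46.7% at 5 months (DESeq2 44.4% and 54.7%), so changes of this size can be missed.

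The comparison of RbKO with WT at 2.5 months asks what loss of Rb1 in Sertoli cells does. In RbKO testes, genes of meiotic germ cells and of cell division fell while steroid-synthesis genes of Leydig cells rose. Skp2, the substrate receptor of a ubiquitin ligase that clears cell-cycle inhibitors, had 892 ± 358 CPM (SD, n = 4) against 35400 ± 10540 in WT (SD, n = 5), a 39.6-fold lower level. Cyp17a1, an enzyme of androgen synthesis in Leydig cells, rose 5.07-fold to 365600 ± 31500 CPM from 72160 ± 25050. Of 96 targets tested with edgeR, 9 were higher and 18 lower in RbKO, 37 had an unadjusted p under 0.05, and all 4 RbKO animals lay on the stated side of the WT mean for each called target. The groups did not overlap for 28 targets, where chance gives 1.59%.

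All 3 tested meiotic targets fell in RbKO. Spo11, which makes the DNA breaks that start recombination, had a log2 fold change of -1.56 (SE 0.33, adjusted p 0.000624). Piwil1, a partner of piRNAs in late spermatocytes and spermatids, changed by -1.76 (SE 0.40, adjusted p 0.00139), and by -2.37 without RbKO replicate 1. Sycp1, a part of the synaptonemal complex, changed by -1.09 (adjusted p 0.0129; 0.0554 without RbKO replicate 2). The list as a whole moved down by fry (adjusted p 1.46e-05; 3 called adjusted over the list alone). Among cyclins and S phase targets 7 of 19 fell and 0 rose (fry adjusted p 0.000198, in either direction 1.13e-18; 7 called adjusted over the list alone). They were Skp2 (-5.31, SE 0.40, adjusted p 2.85e-11), the mitotic cyclin Ccnb1 (-1.95, SE 0.32, adjusted p 3.20e-05), Cdc6, Aurkb, Rrm1, Ccne2 and Pcna. The last 5 passed less firmly and each lost its call without at least 1 library. The adjusted p of Cdc6 was 0.0676 without RbKO replicate 1 and 0.0679 without replicate 4, and that of Rrm1 0.0517 without replicate 2. That of Pcna was 0.0573 without replicate 2 and 0.0525 without replicate 4. For Aurkb it was 0.0528, 0.0760 and 0.0573 without RbKO replicates 1, 2 and 3 and 0.0699 without WT replicate 5, and its change was -2.55 in place of -1.87 without RbKO replicate 4. For Ccne2 it was 0.0573, 0.0970 and 0.0841 without RbKO replicates 2, 3 and 4, and 0.0838 and 0.0549 without WT replicates 2 and 4. Ccne2 also did not pass by limma on the score (0.0610), without the filter (0.0528) or with the libraries over 20% at 0 left out (0.0834). With the 10-day-old animals in the same fit, Cdc6 (0.137), Aurkb (0.0764), Ccne2 (0.0712), Rrm1 (0.0574) and Sycp1 (0.0506) also did not pass, and with only RbKO and WT in the fit Cdc6 (0.0562) and Ccne2 (0.0570) did not.

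Within the RB and E2F family 3 of 8 targets fell in RbKO: Rb1, Rbl2 (p130, a pocket protein of resting cells; -3.04, SE 0.38, adjusted p 6.31e-07) and Rbl1 (p107; -1.02, adjusted p 0.0442). The list moved down (fry adjusted p 0.00454; 4 called adjusted over the list alone). Of the Leydig cell targets Cyp17a1 (2.34, SE 0.32, adjusted p 2.49e-06) and Hsd3b6 (1.38, SE 0.39, adjusted p 0.00759; 0.0558 by limma on the score), both steroid-synthesis enzymes, were called higher. Star, which carries cholesterol into mitochondria, was not (1.08, adjusted p 0.0501). The Leydig list moved up (fry adjusted p 0.000105; 3 called adjusted over the list alone). The adult Sertoli cell list moved up (adjusted p 0.0349) with 1 of 9 targets called, also adjusted over the list alone: Inha, the inhibin alpha subunit (1.05, adjusted p 0.00697; 0.68 and 0.0558 without RbKO replicate 1). The immature Sertoli cell list moved up as well (adjusted p 0.0349) with 1 of 3 called, also adjusted over the list alone: Fst, the activin-binding follistatin (5.51, SE 1.50, adjusted p 0.00623; 7.60 without WT replicate 2). Both Sertoli calls rest on single libraries. Without RbKO replicates 1 and 4 and WT replicates 1, 4 and 5 in turn, the adult list had adjusted p 0.130, 0.0712, 0.0573, 0.0791 and 0.0795. The immature list had 0.0992, 0.123, 0.0573 and 0.0751 without RbKO replicates 1 and 4 and WT replicates 1 and 5. Scaling by the total alone also ended both calls (0.0803 and 0.0669), and so did the deposited score for the adult list (0.0553).

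Outside the lists that moved, Usp1, a deubiquitinase of DNA repair, fell in RbKO (-2.41, adjusted p 2.21e-05), as did Mif4gd (-1.58) and Prcp (-1.18). Cldn3, a tight-junction protein of the blood-testis barrier, fell to 22.7 ± 40.7 CPM from 1040 ± 378 (-5.45, SE 1.05; -8.64 without RbKO replicate 2). Pou5f1, a germline and pluripotency factor, had 1 count in all RbKO libraries and 342 in WT, a ratio of 217 (95% interval 38.7 to 8590, adjusted p 0.00235). Its fitted log2 fold change of -7.19 became -8.82 without RbKO replicate 2 and -6.25 without WT replicate 3. Scd2, a fatty acid desaturase, rose to 54700 ± 8019 CPM from 17360 ± 5260 (1.66, SE 0.33, adjusted p 0.000494). Icam1, an adhesion molecule, rose by 2.39 (adjusted p 0.000828; 1.72 without RbKO replicate 1). Bax, which promotes apoptosis (1.56, adjusted p 0.00314), Aplp1 (1.90) and the reference gene Hprt (1.14) rose too. The remaining lists were not called: apoptosis and p53 (adjusted p 0.406), undifferentiated spermatogonia (0.0723), differentiating spermatogonia (0.156), peritubular (0.989) and reference genes (0.252). Adjusted over the list alone they held 1, 1, 0, 0 and 1 called targets. The peritubular test pointed up while its median and mean were -0.08. The undifferentiated spermatogonia list passed downward without RbKO_E2f3het replicate 3 (0.0224) or dKO replicate 4 (0.0429), and differentiating spermatogonia upward without dKO replicate 3 (0.00655). Without the filter, apoptosis and p53 (0.0320) and reference genes (0.0365) passed upward. Undifferentiated spermatogonia passed downward thinned to equal totals (0.0253), and differentiating spermatogonia upward with the libraries over 20% at 0 left out (0.00716). The annotation holds pseudogenes named after Pcna (2), Ccnb1 (1) and Sycp1 (1). Reads from them were not told apart here, so these 3 are uncertain. Only pseudogenes carrying the symbol of a panel gene were looked for, so copies of other targets may exist.

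**Figure D2:**
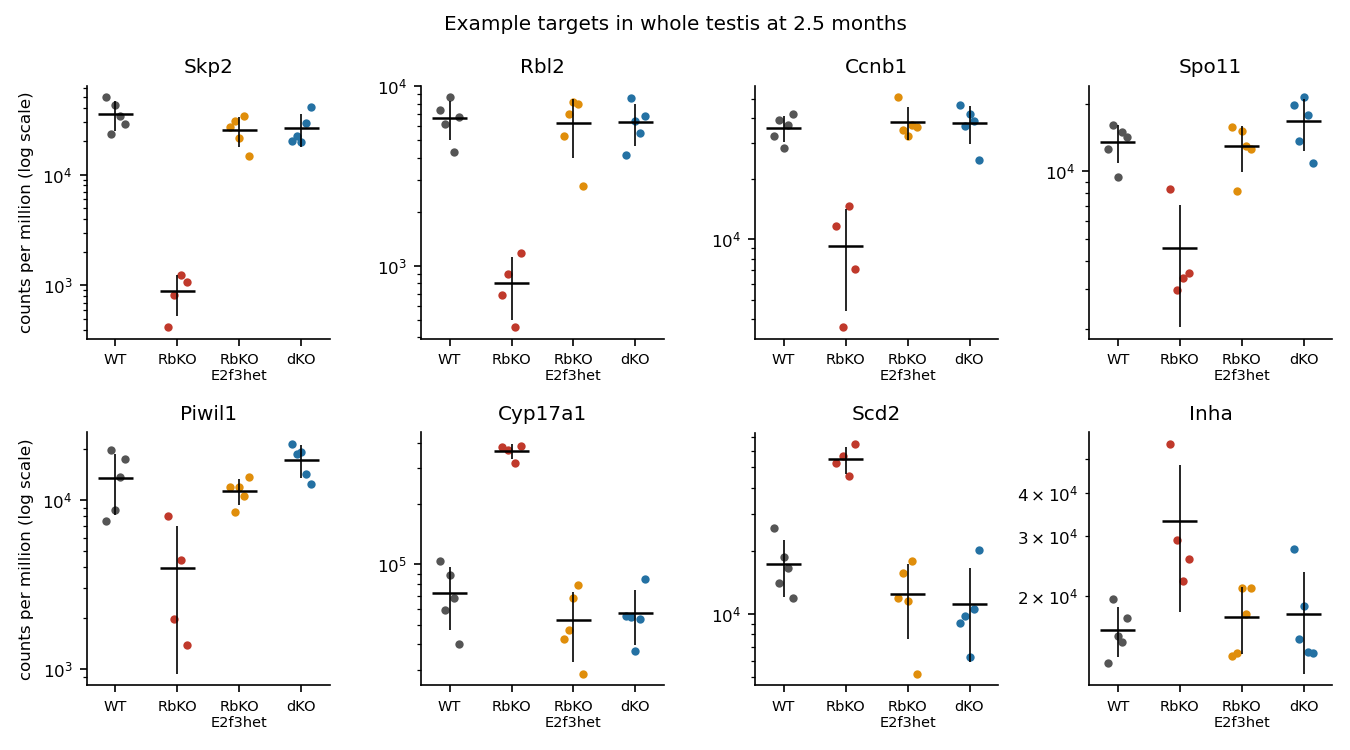
Levels (CPM, log scale on the y axis) of Skp2, Rbl2, Ccnb1, Spo11, Piwil1, Cyp17a1, Scd2 and Inha in each animal of the 2.5-month groups (x axis). For Skp2 the RbKO mean was 892 CPM and the means of the other groups lay at 25340 or above.

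The RbKO_E2f3het and dKO groups were set against WT to ask how the testis looks when E2f3 alleles are also floxed. In both, most of the germ-cell, cell-cycle and Leydig targets that differed in RbKO stood near the WT level. Rrm1 was less clear, at -0.45 in RbKO_E2f3het and -0.60 in dKO on the log2 scale. Its dKO interval (-1.245 to 0.052) held both 0 and the RbKO value of -1.22. Against RbKO it was not called in either group (edgeR adjusted p 0.123 and 0.204). Skp2 had 25340 ± 7518 CPM in RbKO_E2f3het and 26330 ± 8691 in dKO against 35400 ± 10540 in WT (SD, n = 5 each), and Cyp17a1 had 52990 ± 20210 and 57040 ± 17330 against 72160 ± 25050. Over the 27 targets called in RbKO the median absolute log2 fold change was 1.76 in RbKO, 0.34 in RbKO_E2f3het and 0.34 in dKO. The 95% interval of RbKO_E2f3het against WT held 0 for 25 of the 27, and that of dKO for 23. In RbKO_E2f3het 0 of 96 targets were called by edgeR, with 4 at an unadjusted p under 0.05, while DESeq2 called 1 (Fst; 6 unadjusted) and limma on the score 0 (3 unadjusted). Fst (4.70) and Icam1 (1.49), each with adjusted p 0.237, were higher than the WT mean in 5 of 5 RbKO_E2f3het animals, and Fst was called by edgeR without WT replicate 2. In dKO 0 were called by edgeR (7 unadjusted), 0 by DESeq2 (7 unadjusted) and 0 by limma on the score (11 unadjusted). The smallest adjusted p in dKO was 0.472. Of the 27 targets, the dKO interval left out 0 for Fst (4.14, 1.39 to 6.89), Aplp1 (-1.42, -2.46 to -0.38), Rb1 (-1.06, -1.99 to -0.13) and Scd2 (-0.63, -1.25 to -0.01). The Fst interval held its RbKO value of 5.51, while Aplp1 had risen in RbKO (1.90).

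The peritubular and stroma list (Acta2, Cnn1, Col1a1 and Myh11, genes of contractile and matrix-forming cells) was lower in dKO than in WT by fry (adjusted p 0.00945), although 0 of its 4 targets were called, also adjusted over the list alone. Its median log2 fold change was -1.72, with Cnn1 at -1.93, Col1a1 at -2.21, Myh11 at -1.51 and Acta2 at 0.33. Cnn1 had a count of 0 in 3 of 5 dKO libraries and Col1a1 in 2, and in 0 WT libraries. No other list was called in dKO against WT (adjusted p of 0.724 or more), and none in RbKO_E2f3het (0.940 each). Adjusted over the list alone, the immature Sertoli cell list held 2 called targets in RbKO_E2f3het and 1 in dKO. The direction of the test, the median and the mean differed in sign for 1 list in RbKO_E2f3het (immature Sertoli cell) and 4 in dKO (cyclins and S phase, apoptosis and p53, adult Sertoli cell, differentiating spermatogonia).

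Set directly against RbKO, both groups that also carry floxed E2f3 had higher levels of some meiotic and cell-division targets and lower levels of Leydig targets. In RbKO_E2f3het 14 targets were higher and 9 lower than in RbKO (32 unadjusted), and in dKO 16 were higher and 10 lower (37 unadjusted). Skp2 was higher by 4.82 on the log2 scale in RbKO_E2f3het and 4.88 in dKO (SE 0.39 each; adjusted p 1.48e-10 and 1.21e-10). Rbl2 was higher by 2.94 and 2.96 and Ccnb1 by 2.05 and 2.03, in 5 of 5 animals of each group. Spo11 was higher by 1.51 in RbKO_E2f3het and 1.87 in dKO, and Piwil1 by 1.51 and 2.13 (2.12 and 2.73 without RbKO replicate 1). Sycp1 was not called in either (adjusted p 0.128 and 0.111), and 13 of the 19 cyclins and S phase targets were not called in each group. The Piwil1 call in RbKO_E2f3het ended with the 10-day-old animals in the fit (0.0568). Cyp17a1 was lower by -2.79 and -2.68 (adjusted p 1.77e-07 and 3.54e-07), Scd2 by -2.14 and -2.29, and Star by -1.33 (adjusted p 0.0192) and -1.61 (0.00359). Hsd3b6 was lower in RbKO_E2f3het (-1.40, adjusted p 0.00810) and not called in dKO (-0.91, 0.0772). For RbKO_E2f3het the Star call ended without RbKO replicate 1 (0.0569) or RbKO_E2f3het replicate 1 (0.0562), and under scaling by the total alone (0.0693) or the reference genes (0.0783). Pou5f1 was higher than the 1 count of RbKO by a ratio of 122 (21.6 to 4840) and of 294 (52.5 to 11700), the first of which did not pass with only those groups in the fit (0.0543). The fitted changes of Pou5f1, 6.47 in RbKO_E2f3het and 7.80 in dKO, became 8.10 and 9.43 without RbKO replicate 2, 5.70 without RbKO_E2f3het replicate 1 and 6.94 without dKO replicate 3. Usp1, Mif4gd, Prcp, Pcna, Ccne2 and Cldn3 were also higher in both groups, with Cldn3 at 4.11 and 5.40 (7.30 and 8.59 without RbKO replicate 2). Bax was lower in both, at -1.22 and -1.61, and its call in RbKO_E2f3het ended under scaling by the total alone (0.0693) or the reference genes (0.0692).

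Of the 27 targets called in RbKO against WT, 19 were called the other way in RbKO_E2f3het against RbKO and 21 in dKO against RbKO. These counts share the RbKO libraries. With the RbKO libraries split between the comparisons, a median of 2 higher and 6 lower targets were shared for RbKO_E2f3het and 4 and 10.5 for dKO, where independent calls at full size would share 0.844 and 2.62, and 0.938 and 3.00. Against all 3 other adult groups, RbKO was higher for 5 targets (Bax, Cyp17a1, Hprt, Inha and Scd2) and lower for 13, among them Skp2, Rbl2, Ccnb1, Spo11 and Piwil1. The 13 include Cdc6, which lost these calls often. Its adjusted p of 0.0369 in RbKO_E2f3het and 0.0268 in dKO became 0.202 and 0.131 with the 10-day-old animals in the fit, and 0.0753 and 0.262 with only those groups. Without RbKO replicates 1 and 4 it was 0.105 and 0.1000 in RbKO_E2f3het and 0.0886 and 0.0796 in dKO. In RbKO_E2f3het it also ended without RbKO_E2f3het replicates 1 (0.106) or 4 (0.0550) or WT replicates 2 (0.0519) or 3 (0.0529), and in dKO without dKO replicate 2 (0.0510). Of the 5, Bax lost its call in RbKO_E2f3het as given above, and Inha and Hprt lost calls without single libraries or in other fits. In RbKO_E2f3het the adjusted p of Inha was 0.139, 0.0562 and 0.0592 without RbKO replicate 1, RbKO_E2f3het replicate 1 and RbKO_E2f3het replicate 2. That of Hprt was 0.137 and 0.0518 without RbKO replicates 1 and 2, and 0.0553 and 0.0536 without RbKO_E2f3het replicates 1 and 3. With only RbKO_E2f3het and RbKO in the fit they were 0.0989 and 0.0743. In dKO that of Hprt was 0.109 without RbKO replicate 1 and 0.0510 without dKO replicate 2, 0.0751 with only those groups in the fit, and 0.0526 with the libraries over 20% at 0 left out. In dKO Aplp1, an amyloid precursor-like protein, was lower than in RbKO by -3.31 (adjusted p 5.91e-05). Trp53 (-1.48, adjusted p 0.0162; 0.0528 without RbKO replicate 1 and 0.0908 scaled by the reference genes) and Icam1 (-1.74, adjusted p 0.0107; -1.07 and 0.146 without RbKO replicate 1, and 0.0762 by limma on the score) were lower as well. Trp53 has 1 pseudogene named after it in the annotation and is uncertain. Amh, the hormone of immature Sertoli cells, had 0 counts in all 5 RbKO_E2f3het libraries and in 2 of 4 RbKO libraries, while RbKO replicate 4 held 151 of its 164 counts. Over the floor of the group it was at least 78.1-fold lower in RbKO_E2f3het (adjusted p 0.0333), but without RbKO replicate 4 only at least 8.75-fold lower and not called (0.163). The call also ended without any 1 of the RbKO_E2f3het libraries (0.0549 to 0.0672) and by limma on the score (0.262).

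**Figure D3:**
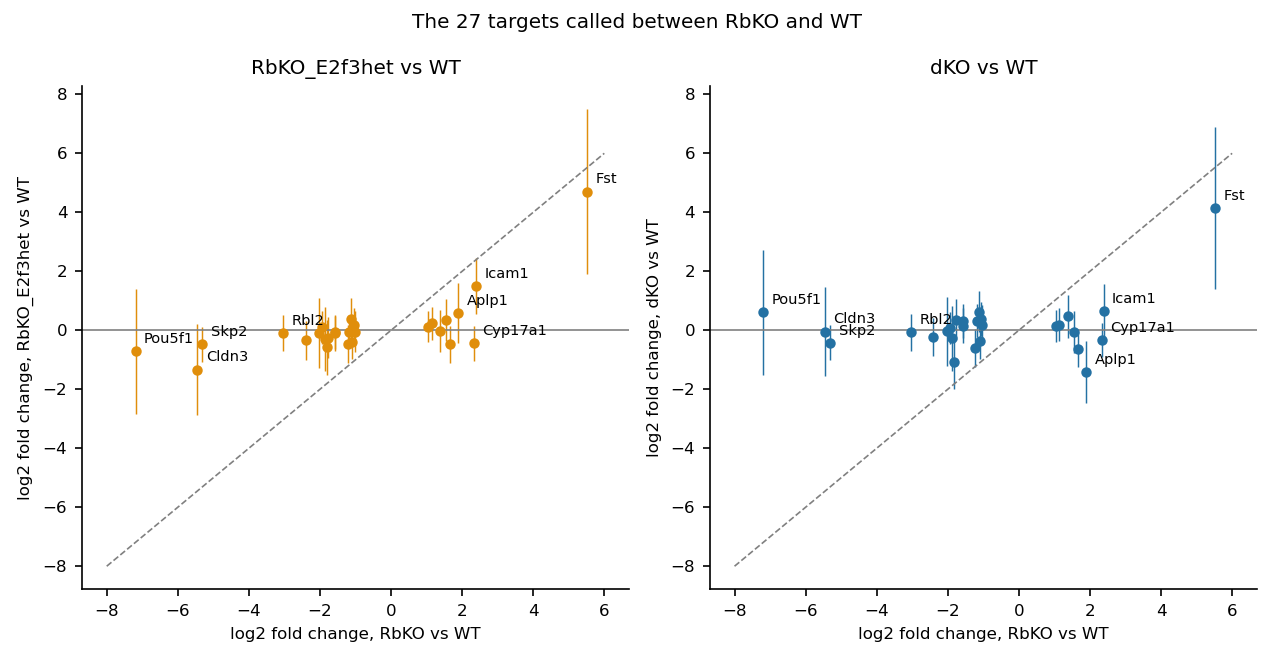
The 27 targets called in RbKO against WT, with the log2 fold change of RbKO against WT on the x axis and that of RbKO_E2f3het or dKO against WT on the y axis. Points are estimates, vertical lines 95% intervals and the dashed line equal change. The interval excluded the RbKO value for 25 targets in RbKO_E2f3het and 24 in dKO. It does not hold the error of the RbKO value, and the targets were picked for that value. Tested directly against RbKO, 19 targets were called in RbKO_E2f3het and 21 in dKO.

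By list, meiotic spermatocyte targets were higher than in RbKO in RbKO_E2f3het (fry adjusted p 4.64e-05; 2 of 3 called, and 3 adjusted over the list alone) and in dKO (7.03e-06; 2 of 3, and 3). Leydig targets were lower in both (3.09e-05 and 4.81e-05; 3 of 3 and 2 of 3, and 3 each over the list alone). Cyclins and S phase (9.87e-05 and 0.000390; 6 of 19 each, and 7 each) and the RB and E2F family (0.00724 and 0.0141; 1 of 8 and 2 of 8, and 1 and 4) were higher. The RB and E2F family did not pass in dKO with the libraries over 20% at 0 left out (0.0788). In the rest of this paragraph the counts are those called adjusted over the list alone. In dKO the adult Sertoli cell (0.0194; 1), differentiating spermatogonia (0.0271; 0) and peritubular (0.00274; 0) lists were also lower than in RbKO. Without RbKO replicate 1 the first 2 of these did not pass (0.0836 and 0.0726), nor did differentiating spermatogonia without RbKO replicate 2 (0.0590). The adult Sertoli cell list also did not pass on the score (0.0818). The immature Sertoli cell list did not pass in RbKO_E2f3het (0.0662; 2) or dKO (0.102; 1), nor did apoptosis and p53 (0.397; 1 and 0.0664; 3) or, in RbKO_E2f3het, differentiating spermatogonia (0.202; 0). Some of these passed downward with 1 library left out. The immature Sertoli cell list did so in RbKO_E2f3het without WT replicate 3, RbKO replicate 3 or dKO replicates 4 or 5 (0.0372 to 0.0488), and in dKO without dKO replicates 4 (0.0374) or 5 (0.0324). Apoptosis and p53 did so in dKO without WT replicate 3, RbKO_E2f3het replicates 2, 3, 4 or 5, or dKO replicates 2 or 5 (0.00488 to 0.0444), and differentiating spermatogonia in RbKO_E2f3het without dKO replicate 3 (0.00785). Other settings also let some pass downward. In RbKO_E2f3het the immature Sertoli cell list passed on the score (0.0272), without the filter (0.0431) and with the libraries over 20% at 0 left out (0.0465). There apoptosis and p53 passed without the filter (0.0431), and differentiating spermatogonia with those libraries left out (0.00698). In dKO apoptosis and p53 passed on the score (0.0223) and without the filter (0.00730).

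Between dKO and RbKO_E2f3het, which differ in the number of floxed E2f3 alleles, 0 of 96 targets were called by edgeR (3 unadjusted), 0 by DESeq2 (6 unadjusted) and 0 by limma on the score (7 unadjusted). The largest difference by p was Aplp1, lower in dKO by -1.99 (SE 0.54, adjusted p 0.0963) in 5 of 5 animals, and called without dKO replicate 3. The peritubular list was lower in dKO than in RbKO_E2f3het (adjusted p 0.0103; 0 called adjusted over the list alone) and no other list passed (0.502 or more), although meiotic spermatocytes passed upward on the score (0.0360). Test, median and mean differed in sign for reference genes in all 3 of these comparisons and for undifferentiated spermatogonia between dKO and RbKO_E2f3het.

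**Figure D4:**
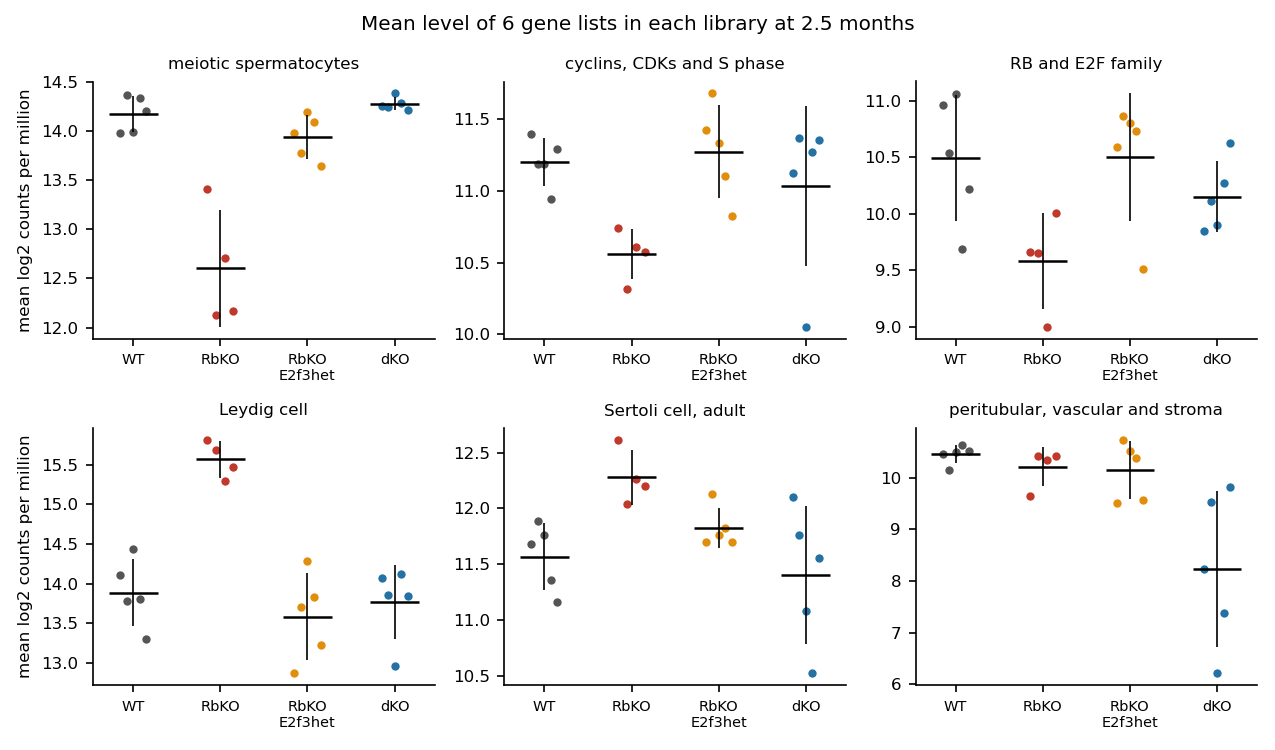
Mean log2 CPM of the targets of 6 gene lists (y axis) in each animal of the 2.5-month groups (x axis). The meiotic spermatocyte mean was 12.6 in RbKO and 14.2 in WT, and the Leydig cell mean 15.6 and 13.9.

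The labels give the 10-day-old animals as controls only, and they show how the panel reads a testis before most meiosis. Compared with 2.5mo_WT, P10_WT had lower meiotic and Leydig targets and higher targets of immature Sertoli cells, differentiating spermatogonia and peritubular cells. Piwil1 was lower by -5.18 (SE 0.87, adjusted p 0.000342) and Spo11 by -3.15 (SE 0.41, adjusted p 4.29e-05). Cyp17a1 had 6034 ± 3351 CPM against 94870 ± 21130 (SD, n = 5 each). Thra, the thyroid hormone receptor alpha, was higher by 1.92 (SE 0.33, adjusted p 0.000399). Amh had 6183 ± 3573 CPM against 137 ± 263 (5.52, SE 1.37, adjusted p 0.00520; 8.49 without 2.5mo_WT replicate 4). Of 96 targets 14 were higher and 22 lower at P10 (43 unadjusted), and 34 did not overlap, where chance gives 0.794%. The split of the calls depends on scaling. With the total alone 30 were higher and 14 lower, and with the reference genes 22 and 17, as the median of all targets moved from 0.00 to 0.72 and 0.31.

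Skp2 (-4.67), Usp1 (-4.37), Rbl2 (-3.83), Mif4gd (-3.69), Prcp (-3.08), Rb1 (-2.11) and Ccnb1 (-1.70) were lower at P10, in 5 of 5 animals each. Fasl, the ligand of the death receptor Fas, had 1 count at P10 and 512 in 2.5mo_WT, a ratio of 416 (95% interval 74.3 to 16500). Its fitted log2 fold change of -8.19 became -9.58 without P10_WT replicate 1. Higher were Ccnd2 (2.86), a cyclin of spermatogonia, Stra8 (1.60), which is needed to enter meiosis, Sox9 (1.66), Inhbb (2.66), Col1a1 (2.75) and Acta2 (1.50). By list, Leydig (adjusted p 2.53e-05; 3 called adjusted over the list alone), meiotic (0.000515; 3) and RB and E2F family targets (0.000611; 3) were lower at P10. The RB and E2F family did not pass with the total alone (0.0776). Immature Sertoli cell (0.000515; 2), differentiating spermatogonia (0.000515; 2), peritubular (0.00272; 2) and adult Sertoli cell targets (0.0161; 3) were higher. Cyclins and S phase went both ways, with 5 higher and 4 lower (one way 0.435, either way 1.02e-12; 9), and passed upward with the total alone (0.000256). Apoptosis and p53 (0.0585; 2), reference genes (0.0548; 1) and undifferentiated spermatogonia (0.935; 0) did not pass one way. In either direction apoptosis and p53 (0.00423) and reference genes (0.0327) did pass. Apoptosis and p53 and reference genes passed downward without 2.5mo_WT replicate 3 (0.000800 and 0.0339) or P10_WT replicate 5 (0.0280 and 0.0242), and with Cyp17a1 left out (0.00643 and 0.0284). They turned upward and passed in 1 setting each, apoptosis and p53 thinned to equal totals (0.000153) and reference genes with the total alone (0.00152). Test, median and mean differed in sign for apoptosis and p53 and for undifferentiated spermatogonia. Age and strain change together in this comparison, and P10_WT replicate 4 had the fewest counts. Of the 18 targets lower in RbKO than in WT, 13 were also lower at P10, and of the 9 higher ones 1 (Bax) was also higher. Among the 13, Sycp1 (-1.09 at P10) lost its P10 call with the reference genes (-0.79, 0.0702) and the total alone (-0.39, 0.320). Cldn3 lost it with the total alone (0.0801), and without 2.5mo_WT replicates 1, 2, 4 or 5 or P10_WT replicates 1 or 3 (0.0589 to 0.0796). Both shared counts use the same WT libraries, and with these split between the comparisons the medians were 8.5 and 1, where independent calls at full size would share 4.17 and 1.33.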

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

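The tests of explanations and the other splits of the samples given here were chosen only after the results were seen. The values marked here are single libraries that stood apart from the rest of their group, with the gap to the nearest library given as a share of the group's range. Of 166 sets of values tested 15 stood out (9.04%), where chance alone marks about 1 in 20.

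In RbKO replicate 1, Mif4gd (0.846) and Spo11 (0.834) were the highest of the group. In RbKO replicate 2, Pou5f1 was the highest (1.00), with 1 count where the other RbKO libraries had 0. In RbKO_E2f3het replicate 5, Rb1 (0.803), Bax (0.771), Usp1 (0.723) and Thra (0.722) were the lowest. In dKO replicate 3, Star was the lowest (0.726). In 2.5mo_WT, Icam1 was lowest in replicate 1 (0.765), E2f3 amplicon 7231987 in replicate 4 (0.764) and Inhbb in replicate 5 (0.841), where Aurkb was highest (0.800). In P10_WT, Fasl was highest in replicate 1 (1.00), with 1 count, and in replicate 4 Star was highest (0.737) and Stra8 lowest (0.744).

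Spermatocyte targets were lower and Leydig targets higher in RbKO than in WT. The share of counts taken by Cyp17a1 does not account for it, since 5 of the other targets of the pattern were called with Cyp17a1 left out and 4 with it, and nor does depth, since 6 were called in each of 20 draws at 127508 counts per library. A smaller share of germ cells would raise every other cell type alike, yet the Leydig list rose over the peritubular list by 1.92 (SE 0.34, exact permutation p 0.00794, the smallest that 126 arrangements can give). Among the peritubular targets Acta2 rose by 0.82 in RbKO (SE 0.32, edgeR adjusted p 0.0525), while Cnn1 (-0.13), Col1a1 (-0.98) and Myh11 (-0.04) did not rise. Of the Leydig targets Cyp17a1 rose by 2.34, Hsd3b6 by 1.38 and Star by 1.08. The Leydig list thus rose more than the peritubular list as a whole, but few targets carry each list. A smaller share of germ cells is not excluded as the cause for each Leydig target, and a change in the Leydig cells themselves, in number or in expression, may contribute. For the spermatocyte targets a smaller share of meiotic germ cells stays a candidate explanation, as these targets were also lower at P10 (median -3.15 on the log2 scale), when the testis holds few such cells.

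Rb1 was lower in RbKO than in WT. Loss of the floxed gene in Sertoli cells is a candidate explanation, since the mean of RbKO_E2f3het and dKO, with the same floxed Rb1, lay at -0.82 against WT (SE 0.40, unadjusted edgeR p 0.0483, 95% interval -1.60 to -0.0431). That mean holds RbKO_E2f3het replicate 5, marked above for Rb1 (428 CPM, next library 2787), and no value without it is given here. Alone, dKO stood at -1.06 (unadjusted edgeR p 0.0344, 95% interval -1.99 to -0.13) and RbKO_E2f3het at -0.58 (-1.51 to 0.34). Fewer meiotic germ cells could also lower Rb1, since it stood at -2.11 at P10 against the adult WT. Both stay open and may act together.

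The peritubular list was lower in dKO than in WT. Depth does not account for it, as the list was called in 20 of 20 draws at equal totals (median adjusted p 0.0101, range 0.00521 to 0.0177). Counts of 0 in weakly counted targets cannot be told apart from lower expression, since Cnn1 and Col1a1 had them in dKO alone and the members without them went both ways (Acta2 0.33, Myh11 -1.51, mean -0.59). Leaving out 1 library at a time kept the list called (adjusted p 0.00253 to 0.0321). Fewer peritubular cells, or less expression in them, were not tested apart from this.

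For each comparison 100 splits of the same samples were counted, the real one included. No other split called as many targets as the real one in RbKO against WT (27 real, at most 13 in another split), RbKO_E2f3het against RbKO (23 and 12), dKO against RbKO (26 and 18) and P10_WT against 2.5mo_WT (36 and 0). For called lists no other split reached the real count in RbKO against WT (6 and 5) or P10_WT against 2.5mo_WT (7 and 3). A share of 1 in 100 was the smallest these splits can give, and the shares were not adjusted over the comparisons. Other splits gave as many called lists in dKO against WT (1 real, at most 1, 3 splits as large), RbKO_E2f3het against RbKO (4, 4 and 3) and dKO against RbKO (7, 7 and 2). Chance therefore cannot be excluded for these lists, nor for the list called between dKO and RbKO_E2f3het (1 real, at most 3, 8 splits as large). For targets at an unadjusted p under 0.05 it cannot be excluded at 2 months (3 real, at most 26; 37), at 5 months (6 and 42; 23), in the difference between the ages (3 and 27; 61), in RbKO_E2f3het against WT (4 and 11; 18), in dKO against WT (7 and 24; 11), or between dKO and RbKO_E2f3het (3 and 19; 41). The splits that gave 26, 42, 27, 24 and 19 such targets, several times the real number, point to a structure of the samples or to targets that move together. Replicates did lie unevenly apart within groups. Chi-square per degree of freedom was 32.6 for 2mo_E2f3KO replicates 4 and 5 but 319 for 2 and 4. In 2.5mo_WT it was 44.2 for replicates 1 and 3 and 53.2 for 2 and 5, but 329.5 for 1 and 5. In 5mo_E2f3KO it was 40.6 for replicates 1 and 3 but 421 for 1 and 4. The fits did not model such subsets, and their cause was not tested.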

How the results depend on the processing

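Leaving out the libraries with over 20% of targets at 0, leaving out Cyp17a1, and thinning to equal totals were chosen only after the data were seen. No paired analysis was possible because the replicate numbers follow the order of the sample list and the labels pair no animals. Some titles hold dates (P10_WT) or close animal numbers, but the labels do not explain them, so litters were not used as blocks. In the E2f3KO comparisons 0 targets were called under each setting run. RbKO_E2f3het against WT gave 0, but 1 with DESeq2 (Fst) and 1 with only the 2 groups in the fit (Icam1), and 0 to 1 over the single libraries left out (Fst without 2.5mo_WT replicate 2). For dKO against WT 0 were called under each setting. dKO against RbKO_E2f3het gave 0, but 1 (Aplp1) with the libraries over 20% at 0 left out, and 0 to 1 over the single libraries left out (Aplp1 without dKO replicate 3). Over the settings other than single libraries, the count was 22 to 33 for RbKO against WT (27 in the report), 21 to 27 for RbKO_E2f3het against RbKO (23), 19 to 34 for dKO against RbKO (26) and 34 to 44 for P10_WT against 2.5mo_WT (36). Over single libraries left out it was 21 to 32, 18 to 26, 21 to 31 and 31 to 42. The lower calls alone ran from 5 to 11 in RbKO_E2f3het against RbKO (9 in the report) and from 5 to 13 in dKO against RbKO (10). All 27 targets called in RbKO were called again with DESeq2, with the total alone and with the reference genes. With the total alone and the reference genes the median of all targets moved from 0.06 to -0.15 and -0.19 in RbKO against WT, and from 0.05 to 0.29 and 0.23 in RbKO_E2f3het against RbKO, where the calls became 18 and 17 higher and 6 lower each. In dKO against RbKO it moved from -0.15 to 0.01 and 0.04. Some named targets were called under every setting that fitted them. They were 18 in RbKO against WT, 13 in RbKO_E2f3het against RbKO, 17 in dKO against RbKO and 25 at P10. A setting that left a target out, as by the filter or with Cyp17a1 left out, was not counted for it. Among the named targets 0 changed sign. The list tests gave 24 to 31 calls (26 in the report), and 22 to 30 over single libraries. At P10 with the total alone, the cyclins and S phase list turned upward (adjusted p 0.000256) and so did the reference genes (0.00152), which follows the median shift of 0.72. Thinned to equal totals, the apoptosis and p53 list turned upward at P10 (0.000153). At full depth only Fasl (-8.19) of its 4 tested targets was lower at P10, while Bax (1.24), Trp53 (0.56) and Apaf1 (0.47) were higher. Fasl had 512 counts over the 2.5mo_WT libraries and 1 at P10. Thinned to 36679 counts per library, it may fall under the mean count of 10 needed for a test. The list would then hold only targets that were higher at P10. Whether Fasl was left out of that fit is not given here. In dKO against RbKO the RB and E2F family list did not pass with the libraries over 20% at 0 left out (0.0788). Another pseudocount was not run, since no limma fit was made on values that need one. At 127508 counts per library, RbKO against WT gave 28 to 31 calls over 20 draws.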

Other observations

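In observations outside the comparisons of single targets, 3 targets that were higher in RbKO than in WT were lower at P10 than in the adult (Aplp1, Cyp17a1 and Hsd3b6), and 0 went the reverse way. The P10 call of Aplp1 (adjusted p 0.0362) ended with the total alone (0.221), the reference genes (0.108), a mean of at least 50 (0.0619) or Cyp17a1 left out (0.0638), and without 2.5mo_WT replicates 1, 2, 3 or 4 or P10_WT replicates 2 or 5 (0.0558 to 0.0996). The Leydig cell targets therefore moved in opposite directions in the RbKO testis and in the young testis, while Spo11 and Piwil1 were lower in both. Sycp1 was lower in both as well, but its P10 call depends on the scaling. Cyp17a1 was the most counted target in RbKO replicates 2, 3 and 4, with 35.2%, 34.5% and 39.6% of all counts. In RbKO replicate 1 that place was held by the ribosomal protein gene Rpl19, with 25.1%. Rpl19 has 10 pseudogenes named after it in the annotation, so its share is uncertain. As mean log2 CPM, RbKO exceeded WT by 1.68 for the Leydig list (SE 0.22) and by 0.71 for the adult Sertoli cell list (SE 0.18), and stood at -0.24 for the peritubular list (SE 0.20). The Leydig and adult Sertoli lists differed by 0.97 (exact permutation p 0.00794, adjusted over 3 pairs of lists 0.0119), a comparison chosen only after the result was seen.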
